A study of Mus musculus with 23 samples.

How the data were processed

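Each of the 23 tumours gave 1 library of droplet single-cell 3' RNA sequencing. Per the labels' protocols, MC38 tumours were dissociated mechanically, cells were enriched on magnetic beads against CD45, and libraries were made with a 10x Genomics kit named as v2 and sequenced on a NextSeq instrument. The deposited values are counts, per the file headers and the values: 1 sparse matrix per tumour holds whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, and every header names version 3.0.2 of the software that wrote it. The aligner and the genome build are not given in the sources used here. Of the 31053 gene identifiers in the matrices, 30934 matched GENCODE vM21, and coordinates printed here are from that annotation on GRCm38. Counts from a gene and an overlapping or near-identical gene could not be told apart, which applies to the paired haemoglobin genes, the histone clusters and the class I H2 genes. The barcodes look like those of a v3 kit instead, judged from memory without a list of either kit's barcodes: 28 of the 42863 start with AAACCC and 0 with AAACCT. All 23 tumours drew on 1 set of barcodes, since only 960 of 16384 possible sequences of 7 bases start them and 100% of the barcodes of tumours 17 to 24 have a start seen in tumours 1 to 16. Whether other reagents differed cannot be told from the sources used here. The labels give no batch. They name a harvest on day 20 and another on day 24 without saying which tumours belong to which.

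Total counts per tumour ran from 8004504 to 25707703 and summed to 322900355 over 42863 barcodes (781 to 3596 per tumour). Barcodes with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial counts passed, 24207 in all. Of the barcodes, 10806 held too few genes and 16542 exceeded the mitochondrial limit. Within each tumour the barcodes closest to simulated doublets were removed at a rate of 0.8% per 1000 barcodes, which took out 401 barcodes (1.66%) and left 23806 cells (465 to 1967 per tumour, median 2107 to 14718 UMIs). No correction for free RNA was applied. The 42 pairs of tumours within a group differed by more than counting noise (chi-square per degree of freedom 13.8 to 428), which excludes only that 2 of them are the same library sequenced again.

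Cells were clustered with Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 (2000 variable genes, 30 principal components, 20 neighbours, Leiden resolution 1.0). T and NK clusters were clustered again. Clusters were named from markers fixed before the data were examined, as were the gene lists, the comparisons, the tests and a first set of other settings. The way of scoring those markers was not kept as first written and was changed 2 times after the clusters were seen. The first version used folds over all other cells, which failed because macrophage-like cells made up most of them. The second took the class with the highest mean marker level, each marker scaled to its highest cluster, and the third, used here, took that scale from the main clustering for every setting. A cluster stayed unnamed with under 3 markers raised over the clusters of other classes, with more markers of another class among its 10 leading genes, or with a low UMI count and no own marker among them. Of the CD8 T-like sub-clusters, 2 were led by histone or cell-cycle genes (Hist1h2ap, Ccnb2), 1 carried the replication genes Pclaf, Hells and Mcm3, and 1 carried the heat-shock genes Hspa1a and Hspa1b among its leading genes. A sub-cluster of 134 cells with both T cell and macrophage genes stayed unnamed.

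Counts were summed per tumour over the cells of a class, using tumours with at least 20 cells of it. Sums were tested with edgeR 4.0.16 (R 4.3.3), using TMM scaling, its expression filter and the robust quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 5 groups were fitted together. The 6 comparisons set each treatment against Control, Bispecific against Combination, and the groups given both specificities against the groups given 1 (dual against single). Tests are two-sided unless a sentence says otherwise. Gene lists with at least 5 measured members (23 lists in macrophage-like and 20 in CD8 T-like cells) were tested with fry of limma 3.58.1. Its p tests whether the members of a list move, on balance, 1 way, and does not compare them with other genes. Camera with an estimated correlation, which does compare with other genes, was the alternative. Shares of cells were compared by exact permutation, or by 100000 resamples for dual against single and for the test over all 5 groups, with adjustment over 9 classes or over 54 pairwise tests.

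Genes named in the text follow a fixed rule: the antibody targets, up to 12 of the largest rises and falls among passing genes with mean log2 CPM (counts per 1e6) of at least 4 and the same direction in every tumour of the first group, up to 4 members with the smallest p per list, and the 5 smallest p where fewer than 5 genes passed. Immunoglobulin and T cell receptor segments, haemoglobin genes, predicted genes and genes under 0.1 of their level in another class were not eligible as largest changes. A subset of the genes this rule gives is printed, chosen after their values were seen.

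On counts simulated from the real tumours for Bispecific against Control, the same fit recovered 69.4% of genes lowered and 78% of genes raised by a log2 fold of 1 in macrophage-like cells (10810 genes), and 32% and 34% at a log2 fold of 0.5, with 7 of 10611 unchanged genes called. In CD8 T-like cells (8825 genes) these were 49% and 68%, 10% and 2.04%, with 3 of 8627 unchanged genes called. None of 23 and 20 unchanged lists were called. Genes were simulated independently of each other and without a difference between early and late tumour numbers. These counts therefore do not measure false calls that come from correlated list members or from such a difference. That first set was DESeq2 1.42.0, relative log expression size factors, no expression filter, only the compared groups in the fit, stricter cell filters (1000 UMIs, 500 genes, 5% mitochondrial), no doublet removal, other Leiden resolutions (0.5 and 2.0), other share scales and leaving out each tumour in turn. Settings added after seeing the data put runs of 8 tumour numbers or the split after tumour 16 into the fit, removed each library's trend with transcript length, or kept only tumours 1 to 16 or the tumours of 1 run. Other boundaries between tumour numbers were also looked at before these were chosen. Figures were drawn with matplotlib 3.10.9. Tumour 5 is not analysed here. Classes with too few cells per tumour were left out of gene tests.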

Results

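RNA of single cells was measured in 23 MC38 colon carcinoma tumours grown in C57BL/6 mice, after enrichment of cells carrying CD45, the marker of white blood cells. The groups were Control (vehicle, tumours 1 to 4, n = 4), aCD47 (antibody against CD47, tumours 6 to 9, n = 4), aPDL1 (antibody against PD-L1, tumours 10 to 14, n = 5), Combination (both antibodies, tumours 15 to 19, n = 5) and Bispecific (1 antibody binding CD47 and PD-L1, tumours 20 to 24, n = 5). Total UMI counts were 17695601, 10564324, 12399568 and 9942256 in Control, 9374467, 20821059, 14496253 and 12111446 in aCD47, and 14328241, 25354630, 9426192, 8503751 and 8990184 in aPDL1, in order of tumour number. They were 12309231, 10589716, 12259373, 13684426 and 13851136 in Combination and 8004504, 21532056, 17112056, 13842182 and 25707703 in Bispecific. Every p-value measures the spread between these tumours.

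Monocyte/macrophage-like cells, named from genes such as Lyz2, C1qa and Csf1r, were the largest class with 16604 of 23806 cells. T-like cells (Cd3e, Cd3g) numbered 3314, with 2302 CD8 T-like (Cd8a, Cd8b1), 650 regulatory T-like (Foxp3) and 240 naive/memory T-like cells among the sub-clusters. NK-like cells (Ncr1, Gzma) numbered 580, neutrophil-like cells (S100a8, S100a9) 374, and dendritic cells 308 cDC2-like (Cd209a), 246 cDC1-like (Xcr1), 167 migratory (Ccr7) and 36 plasmacytoid (Siglech). There were 83 B-like cells (Cd79a). Outside the immune classes were 1803 fibroblast-like cells led by Rhox5, Cald1, Tnnt2, Sparc and Col6a1, markers that do not part MC38 cells from fibroblasts, 106 tumour epithelial-like cells (Krt8, Krt18) and 185 erythroid-like cells, 40% of them from 1 tumour. Per tumour, 301 to 1261 macrophage-like cells entered the gene tests (23 tumours, 3409294 to 12345840 UMIs). CD8 T-like cells numbered 25 to 317 (21 tumours, 342214 to 3370838 UMIs), as tumours 4 and 17 held under 20 cells, leaving 3 Control and 4 Combination tumours.

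The first question was whether the make-up of the immune cells differed between groups. Of 9 classes tested over all 5 groups, 4 passed by permutation: macrophage-like (adjusted p = 0.00783), T-like (0.0139), cDC2-like (0.0139) and CD8 T-like cells (0.017). Macrophage-like cells made up 79.7 ± 1.79% of immune-named cells in Control (mean ± SD, n = 4), 74.1 ± 4.08% in aCD47 (n = 4), 77.1 ± 4.69% in aPDL1 (n = 5), 84.5 ± 2.96% in Combination (n = 5) and 68.9 ± 7.21% in Bispecific (n = 5). CD8 T-like cells, which kill target cells, made up 5.93 ± 2.67%, 10.3 ± 1.87%, 9.82 ± 5.32%, 6.52 ± 3.71% and 17.1 ± 6.02%, and all T-like cells 10.5 ± 2.53%, 15.5 ± 2.7%, 14.3 ± 5.82%, 9.19 ± 3.66% and 23.3 ± 7.95%, in the same order. The shares of cDC2-like cells, which present antigen to T cells, were 1.83 ± 0.239%, 2.62 ± 1.53%, 1.16 ± 0.484%, 0.643 ± 0.46% and 1.39 ± 0.425%. Adjusted p was 0.145 for regulatory T-like, 0.243 for NK-like, 0.357 for neutrophil-like, 0.444 for naive/memory T-like and 0.806 for cDC1-like cells. The CD8 T-like call was lost without Bispecific tumour 22 (adjusted p = 0.0583) or 23 (0.0654), and without aPDL1 tumour 12 the regulatory T-like share passed (0.0143). On log2 shares the CD8 T-like call was also lost (0.0578) and the regulatory T-like share passed (0.045), and the macrophage-like call when all kept cells were the denominator (0.0533).

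No pair of groups passed for any class after adjustment over 54 tests (lowest adjusted p = 0.171, permutation). Bispecific minus Combination was -15.6 points for macrophage-like (exact p = 0.00794, the smallest possible with 5 against 5), 14.1 for T-like, 10.6 for CD8 T-like and 2.75 for regulatory T-like cells (each exact p = 0.0159). Bispecific minus Control was 11.2 points for CD8 T-like cells (exact p = 0.0238), and Combination minus Control was -1.19 for cDC2-like (0.0159) and 4.8 for macrophage-like cells (0.0238), the latter turning to -0.126 points with all kept cells as the denominator. Macrophage-like, T-like and CD8 T-like shares in aCD47 minus Control were -5.53, 4.98 and 4.39 points (each exact p = 0.0571, smallest possible 0.0286). For aPDL1 minus Control the lowest exact p was 0.0556, for cDC2-like cells at -0.672 points. For dual against single the cDC2-like difference was -0.872 points (permutation p = 0.0439). aCD47 tumour 6, at 4.59% against 1.38 to 3.06% in the other aCD47 tumours, raised the mean on the single side.

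**Figure D1:**
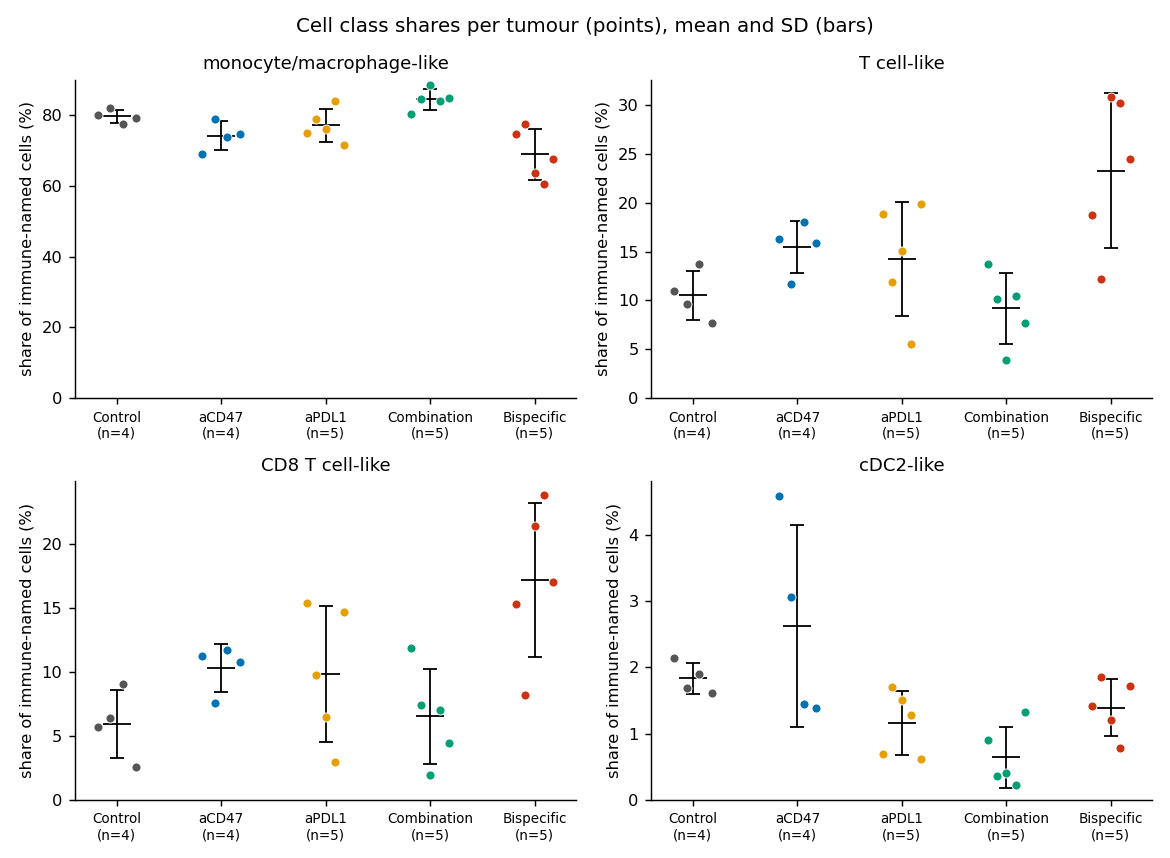
Share of immune-named cells per tumour for macrophage-like, T-like, CD8 T-like and cDC2-like cells, with mean and SD. The mean CD8 T-like share was 5.93% in Control and 17.1% in Bispecific.

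A measured feature of the libraries stands beside every gene comparison. AY036118 (ENSMUSG00000105361, GRCm38 chr17:39847113-39848035), a gene in a ribosomal RNA repeat, was at 285 to 1510 CPM (counts per 1e6) in macrophage-like cells of tumours 1 to 16 and at 75.8 to 149 in tumours 17 to 24. The ranges in CD8 T-like cells were 179 to 1020 and 34.6 to 80.9. Combination tumours 15 (684) and 16 (836 CPM in macrophage-like cells) lay on the side of the controls and the other 3 Combination tumours with Bispecific, so that Control and Bispecific share no part of this split. The tumour-number runs 1 to 8, 9 to 16 and 17 to 24 alone gave 2730 genes in macrophage-like cells and 818 in CD8 T-like cells. Treatment group alone gave 1207 and 300. The runs were chosen after the data were seen and divide the tumours into fewer parts than the groups do. These counts therefore do not rank run above treatment. Group added to run gave 0 genes in both classes, and run added to group gave 21 and 0.

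**Figure D2:**
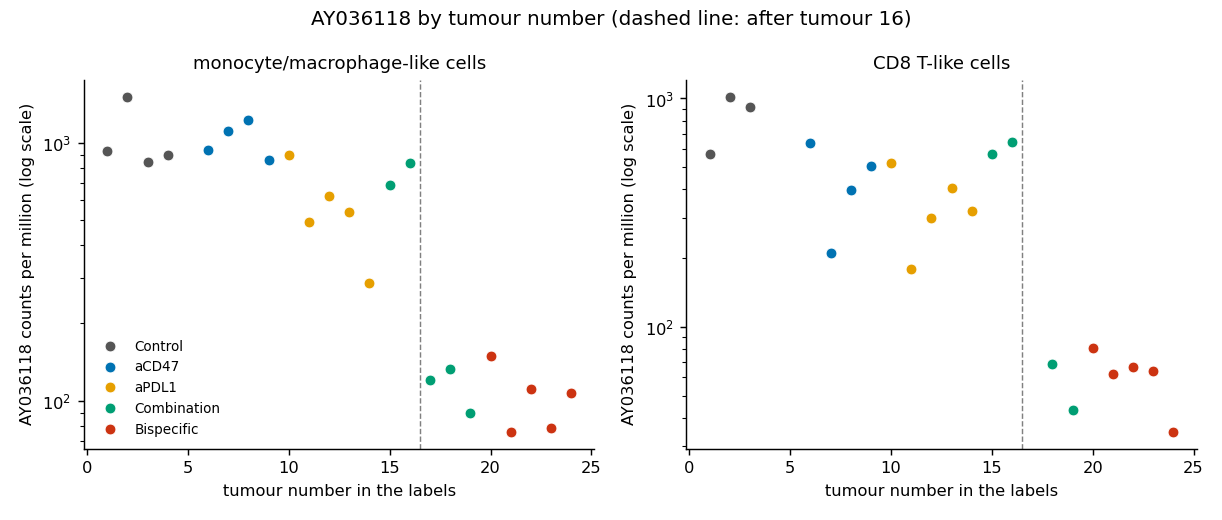
AY036118 in macrophage-like and CD8 T-like cells against tumour number, log axis, with a dashed line after tumour 16. In macrophage-like cells it was at 684 and 836 CPM in Combination tumours 15 and 16 and at most 149 in tumours 17 to 24.

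Antibody against CD47 alone was compared with Control to ask what removing this inhibitory signal does by itself. In macrophage-like cells Tsc22d3, a glucocorticoid-induced gene, had a log2 fold of 0.77 ± 0.14 (SE; 134 against 78.6 CPM, adjusted p = 0.12, n = 4 against 4). Hells, a chromatin gene of dividing cells, was at -0.89 ± 0.18 (adjusted p = 0.262), Klf9 at 0.90 ± 0.19 (0.341) and Cnot3 at 0.52 ± 0.12 (0.431). The target gene Cd47 itself was at 0.25 ± 0.11 (446 against 375.5 CPM, adjusted p = 0.803) and its receptor gene Sirpa at -0.07 ± 0.11 (0.958). Of the interferon-gamma response genes 22 of 22 measured members were higher with none passing (list adjusted p = 0.278), and of the proliferation genes 24 of 25 were lower (0.277, median log2 -0.25). For the Fc receptor and phagocytosis genes the test pointed up (0.234), with median 0.07 and mean -0.01. Inflammatory cytokines and NF-kB targets pointed up at 0.47 with median 0.20 and mean -0.18, 1 member higher and 1 lower when adjusted over the list alone.

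Neither class held a passing gene with aCD47. edgeR gave 0 of 10933 genes in macrophage-like and 0 of 8954 in CD8 T-like cells, with 666 and 383 at unadjusted p under 0.05, and DESeq2 gave 1 and 0. Fitting only the compared groups gave 3 and 0, the run in the fit 1 and 0, and leaving out aCD47 tumour 6 gave 1 in macrophage-like cells. Among CD8 T-like cells (n = 4 against 3) the smallest p belonged to Pif1 at -1.98 ± 0.50, Lmna at -1.17 ± 0.30, Sigirr at 0.67 ± 0.18 and Arl6ip1 at -0.54 ± 0.14 (each adjusted p = 0.974). Pdcd1, which encodes the PD-1 receptor, was at 0.03 ± 0.20, and no list passed (lowest adjusted p = 0.894).

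Antibody against PD-L1 alone was compared with Control to ask what blocking this ligand does by itself. In macrophage-like cells the Fc receptor and phagocytosis genes rose as a list (adjusted p = 0.00155; adjusted p = 0.114 with an estimated correlation). Of its 17 measured members 13 were higher and none passed alone, 2 when adjusted over the list alone. Fcgr3, a receptor for antibody, was at 0.35 ± 0.08 (961 against 756 CPM, adjusted p = 0.245, n = 5 against 4) and Fcgr4 at 0.73 ± 0.22 (454.5 against 273, 0.29). MHC class I antigen presentation had 15 of 16 members higher without passing (0.0761, 5 adjusted over the list alone), among them B2m at 0.33 ± 0.09 and H2-T23 at 0.34 ± 0.11. The target gene Cd274 was at 0.25 ± 0.25 (135 against 113.5 CPM, adjusted p = 0.807). Cytotoxic effector genes, which macrophages carry little of, had 12 of 13 higher (0.0582, 3 over the list alone) beside T cell RNA with 9 of 9 higher (0.417). Erythrocyte RNA had 5 of 5 lower, median -0.84, while its test pointed up (0.903). Nr4a2, an immediate early gene, was at 1.78 ± 0.38 and Agps at -0.45 ± 0.09 (each 0.245). With the run in the fit or with only tumours 1 to 16 no list passed. The Fc receptor list passed without each tumour, joined by 3 lists without aPDL1 tumour 12 and by 1 without aPDL1 tumour 10 or Control tumour 1, 2 or 4, and with the split after tumour 16 by cytotoxic genes (0.0434).

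No gene passed with aPDL1 in either class. edgeR gave 0 and 0 genes, with 1065 in macrophage-like and 584 in CD8 T-like cells at unadjusted p under 0.05, and DESeq2 gave 30 and 0. Only the compared groups in the fit gave 0 and 1. Leaving out aPDL1 tumour 10 gave 1 gene in macrophage-like cells, and leaving out aPDL1 tumour 12 or 13 gave 1 in CD8 T-like cells. Serpinb9 in CD8 T-like cells (n = 5 against 3), an inhibitor of granzyme B, was at 1.08 ± 0.23 (adjusted p = 0.52) and Rps6 at 0.37 ± 0.09. Of the MHC class II genes 8 of 8 were higher (list adjusted p = 0.239) and of the type I interferon-stimulated genes 24 of 27 lower (0.658).

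Both antibodies together were compared with Control to ask what the joint treatment does. In macrophage-like cells Ctsd, which encodes a lysosomal protease (ENSMUSG00000007891, chr7:142375911-142388038), rose (n = 5 against 4) by log2 0.70 ± 0.13 (1392 against 858 CPM, adjusted p = 0.00413), Ctsb by 0.47 ± 0.10 (0.00779), Cd68 by 0.43 ± 0.08 (0.00434) and Serpinb6a by 1.29 ± 0.29 (0.0144). Folr2, a folate receptor of tissue-resident macrophages (chr7:101839988-101857194), rose by 2.08 ± 0.56 (55.5 ± 31.3 against 12.9 ± 5.21 CPM, SD, 0.0312), Selenop by 0.66 ± 0.20 (0.0447), Lyz2 by 0.45 ± 0.12 (0.0288) and the transcription factor gene Klf2 by 1.12 ± 0.31 (0.0365). Idi1 fell by 0.90 ± 0.16 (0.00379) and Cyp51 by 0.74 ± 0.19 (0.0241), as did Myc by 0.62 ± 0.16 (0.0196), the RNA helicase gene Dhx9 by 0.89 ± 0.14 (0.00271) and the histone gene Hist1h1b by 1.82 ± 0.40 (0.0118). Without 1 tumour, the highest adjusted p was 0.0848 for Folr2 and 0.0946 for Lyz2 (Control tumour 2), 0.132 for Selenop (Control tumour 4), 0.097 for Klf2 and 0.093 for Cyp51 (Control tumour 1), and 0.0727 for Myc (Control tumour 2). The other genes of this paragraph kept their call in every such fit.

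Red blood cell RNA also rose in the macrophage-like sums: the globin gene Hbb-bt (chr7:103812524-103813996) by 4.31 ± 0.98 (183 ± 139 against 7.9 ± 12.9 CPM, adjusted p = 0.0154) and the haem synthesis gene Alas2 by 3.43 ± 0.81 (4.91 against 0.331, 0.0149). Over all barcodes haemoglobin genes took a mean of 0.68% of UMIs in Control and 13.7% in Combination. Free RNA was not corrected for, so this rise cannot be told apart from it. As a list, erythrocyte RNA rose (adjusted p = 0.00971; adjusted p = 0.313 with an estimated correlation), with 2 of 5 members passing and 5 adjusted over the list alone. Complement, lipid and scavenger genes rose (0.0179; adjusted p = 0.313 with an estimated correlation), with 4 of 20 passing up and 5 over the list alone, and so did macrophage RNA (0.0179; adjusted p = 0.313 with an estimated correlation; 2 of 10 up). Fc receptor and phagocytosis genes rose (0.00971; adjusted p = 0.382 with an estimated correlation): of 17 members 2 rose, Cd68 and Fcgr3 (by 0.30 ± 0.08, 0.0241), and 1 fell, Elmo1 (by 0.28 ± 0.08, 0.0253), with 4 and 1 over the list alone. Leaving out Control tumour 3 raised the adjusted p of Fcgr3 to 0.0626 and leaving out Control tumour 1 that of Elmo1 to 0.0809. Mitochondrial transcripts split, with 3 of 13 rising (mt-Co2 by 0.36 ± 0.09, 0.0154; 0.0587 without Control tumour 2) and 2 falling (mt-Nd4l by 1.04 ± 0.23, 0.0111). Their list pointed up at adjusted p = 0.499, median 0.23 and mean -0.03. MHC class I had 14 of 16 members higher (0.144), and type I interferon-stimulated genes 17 of 28 lower (0.569).

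In all 264 genes rose and 537 fell in macrophage-like cells with Combination (801 of 10933), and none of the 801 was called with the run, with the split after tumour 16, or with only tumours 1 to 16 in the fit. Tumours 1 to 16 hold only tumours 15 and 16 of Combination. With each library's trend with transcript length removed, 255 genes passed. Risen genes had a median transcript length of 1924 bases, fallen genes 5536, all tested genes 3301.5. The 801 became 382, 404, 474 and 460 without Control tumours 1, 2, 3 and 4, and 387 and 437 without Combination tumours 17 and 18. Fitting only the compared groups gave 473. No list passed with the run or with tumours 1 to 16 only. With the split, erythrocyte RNA alone of the 4 lists passed, beside cytotoxic genes and tumour and stroma RNA (each 0.0344), and with the length trend removed the erythrocyte and Fc receptor lists did (each 0.0138). Those 2 also passed without each tumour, while complement, lipid and scavenger genes were lost without Control tumour 1 or 2 or Combination tumour 18 and macrophage RNA without Control tumour 2 or 4 or Combination tumour 18. Without Combination tumour 19 cytotoxic genes (0.0206) and tumour and stroma RNA (0.00845) passed as well.

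In CD8 T-like cells (n = 4 against 3) Aspm, a spindle gene (chr1:139454772-139494091), fell with Combination by 2.30 ± 0.40 (11.3 against 60 CPM, adjusted p = 0.0163), Ckap2l by 1.88 ± 0.33 (0.0163), Kif20b by 1.51 ± 0.31 (0.0297) and Smc4 by 0.73 ± 0.15 (0.0297). Lat, an adaptor of the T cell receptor (ENSMUSG00000030742, chr7:126363824-126369570), rose by 0.72 ± 0.13 (402 ± 72.6 against 241 ± 6.5 CPM, 0.0163) and Znhit2 by 1.06 ± 0.22 (0.0297). Without Control tumour 1 their adjusted p were 0.0903 (Aspm, Ckap2l, Lat), 0.153 (Kif20b, Smc4) and 0.17 (Znhit2). Of the proliferation genes 19 of 25 were lower and none passed (list 0.271, 9 adjusted over the list alone). Fc receptor and phagocytosis genes rose as a list (0.0255; adjusted p = 0.394 with an estimated correlation; 7 of 10 higher, none passing, 2 over the list alone), beside macrophage RNA with 8 of 8 members higher (0.394). That call was lost without Control tumour 1, 2 or 3 or Combination tumour 16 or 18 and with the run, the split, the length trend removed or tumours 1 to 16 only. The count was 21 (4 up, 17 down). It was 2, 12 and 0 without Control tumours 1, 2 and 3, 101, 0 and 7 without Combination tumours 15, 16 and 18, 0 with the run, 5 with the split, 11 with the length trend removed, 0 with tumours 1 to 16, 114 in DESeq2, 9 with only the compared groups, 45 without the expression filter and 10 with the stricter cell filter. AY036118 differed between the tumours of this comparison as given above.

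The bispecific antibody was compared with Control to ask what binding CD47 and PD-L1 by 1 molecule does. In macrophage-like cells (n = 5 against 4) Selenop, a selenium carrier, rose by 0.82 ± 0.20 (adjusted p = 0.0103), Folr2 by 2.10 ± 0.56 (57.4 ± 39.9 CPM, 0.0196), Ctsb by 0.42 ± 0.10 (0.00706), Tsc22d3 by 0.72 ± 0.13 (0.00136), Klf2 by 1.21 ± 0.31 (0.0159) and Lyz2 by 0.45 ± 0.12 (0.0184). MHC class I genes H2-D1 (ENSMUSG00000073411, chr17:35262730-35267499) and H2-K1 rose by 0.39 ± 0.09 (3931 ± 504 against 3006 ± 229 CPM, 0.0067) and 0.37 ± 0.11 (0.032). Ifit2 (ENSMUSG00000045932, chr19:34550694-34576419) fell by 0.94 ± 0.21 (124 ± 10.3 against 238 ± 50.7 CPM, 0.00631), Ifih1 by 0.79 ± 0.17 (0.00469), Stat2 by 0.50 ± 0.13 (0.0133) and Slfn9 by 1.16 ± 0.20 (0.00115). The inhibitory receptor gene Lilrb4a fell by 1.08 ± 0.24 (0.00724), Hist1h1e by 2.39 ± 0.36 (0.000491) and AY036118 by 3.33 ± 0.56 (104 ± 29.7 against 1044 ± 313 CPM, 0.00115). Without 1 tumour the highest adjusted p was 0.0618 for Folr2, 0.0737 for Lyz2 and 0.065 for Stat2 (Control tumour 2), 0.133 for H2-K1 (Control tumour 4) and 0.0513 for Klf2 (Control tumour 1). Fitted with the run, Ifit2 stood at 0.09, Ifih1 at 0.04, Stat2 at 0.08, Slfn9 at 0.07 and Lilrb4a at 0.44.

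Among the lists in macrophage-like cells with Bispecific, Fc receptor and phagocytosis genes rose (adjusted p = 0.00202; adjusted p = 0.54 with an estimated correlation). Of 17 members 4 rose, among them Fcgr3 by 0.35 ± 0.08 (0.00511), Cd68 by 0.32 ± 0.08 (0.0124) and Rac2 by 0.26 ± 0.07 (0.015), and Elmo1 fell by 0.28 ± 0.08 (0.0167), with 6 and 1 over the list alone. Without Control tumour 4 Rac2 had an adjusted p of 0.0757, and without Control tumour 1 Elmo1 of 0.0604. Complement, lipid and scavenger genes rose (0.0416), cytotoxic genes rose (0.0393) and macrophage RNA rose (0.0393), each with adjusted p = 0.54 with an estimated correlation, by 3 of 20, 0 of 13 and 1 of 10 passing members and 5, 0 and 2 over the list alone, in that order. T cell RNA had 8 of 9 members higher in the same sums (0.734). Type I interferon-stimulated genes had 25 of 28 members lower, 5 passing, and did not pass as a list (0.32, median -0.29). MHC class I had 3 of 16 rising (list 0.112, 7 up and 1 down over the list alone) and MHC class II 1 of 11 (0.241). Mitochondrial transcripts pointed up at 0.78 with 5 of 13 rising (mt-Co2 by 0.38 ± 0.09, 0.00552) and 3 falling (mt-Nd6 by 1.15 ± 0.19, 0.000602), median 0.26 and mean -0.09. With the run, mt-Co2 stood at -0.03 and mt-Nd6 at 0.22.

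In all 394 genes rose and 831 fell in macrophage-like cells with Bispecific (1225 of 10933), 0 with the run or the split after tumour 16 in the fit and 653 with the transcript-length trend removed. Risen genes had a median transcript length of 2133 bases and fallen genes 5441. No list passed with the run or the split. With the length trend removed the Fc receptor list alone passed (0.00317). Without Control tumour 1 the complement, lipid and scavenger list was lost, and only the Fc receptor and phagocytosis list passed without Control tumour 2, 3 or 4 or Bispecific tumour 20, 23 or 24 (adjusted p 0.00431 to 0.0136).

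**Figure D3:**
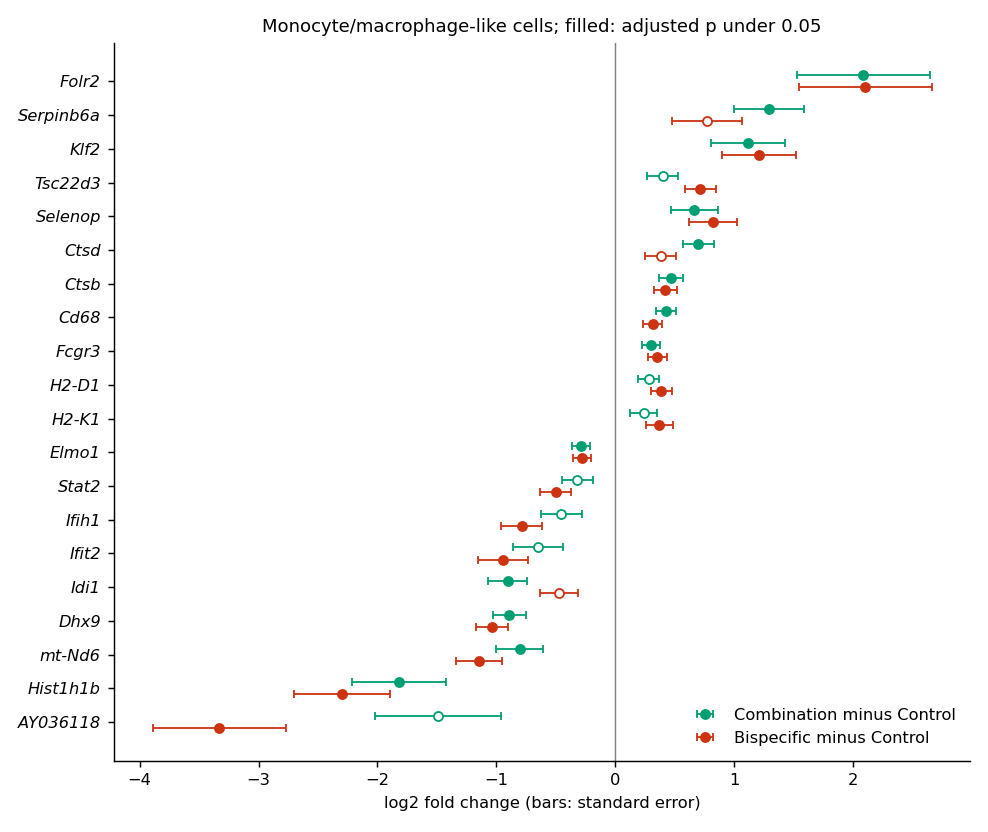
Log2 fold ± SE of 20 genes in macrophage-like cells for Combination and Bispecific against Control, filled where adjusted p was under 0.05. Ctsb was at 0.47 ± 0.10 and 0.42 ± 0.10.

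In CD8 T-like cells with Bispecific (n = 5 against 3) Cst7, a cystatin of killer cells (ENSMUSG00000068129, chr2:150570415-150578944), rose by 0.65 ± 0.18 (411.5 against 261 CPM, adjusted p = 0.0363), the adhesion genes Itgb2 by 0.48 ± 0.13 (0.0252) and Icam1 by 0.56 ± 0.17 (0.0404), the receptor gene Cd3e by 0.47 ± 0.13 (0.0249), and the glycolysis and glucose uptake genes Gapdh by 0.41 ± 0.10 (0.00996) and Slc2a1 by 0.78 ± 0.21 (0.0276). B2m, the light chain of MHC class I, rose by 0.32 ± 0.10 (0.0432), Tapbp by 0.38 ± 0.12 (0.0486), Rac2 by 0.41 ± 0.11 (0.0189), Acp5 by 0.88 ± 0.20 (0.01) and S1pr4 by 0.78 ± 0.19 (0.0155). The cell-cycle gene Mki67 (ENSMUSG00000031004, chr7:135689784-135716361) fell by 1.61 ± 0.38 (111 ± 32.5 against 335 ± 93.4 CPM, 0.0208), the inhibitory receptor gene Tigit by 1.33 ± 0.37 (3.83 against 9.86 CPM, 0.0274), Hist1h1e by 2.69 ± 0.37 (0.000754), mt-Nd6 by 1.02 ± 0.25 (0.0147) and AY036118 by 3.78 ± 0.63 (61.7 ± 16.8 against 837 ± 233 CPM, 0.00321). Only AY036118 and Hist1h1e kept their call without each tumour. The highest adjusted p was 0.162 for Cst7, 0.149 for Itgb2, 0.0953 for Gapdh, 0.189 for Tapbp, 0.0832 for Acp5, 0.23 for Tigit and 0.101 for mt-Nd6 without Control tumour 2. It was 0.201 for Icam1, 0.131 for Cd3e, 0.221 for B2m and 0.132 for Rac2 without Control tumour 3, and 0.144 for Slc2a1, 0.105 for S1pr4 and 0.105 for Mki67 without Control tumour 1. With the run in the fit Tapbp stood at -0.17, Hist1h1e at 0.18 and mt-Nd6 at 0.41.

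Cytotoxic genes rose as a list in CD8 T-like cells with Bispecific, 21 of 22 higher, 1 passing and 2 over the list alone. MHC class I rose with 15 of 16 higher, 2 passing and 7 over the list alone, and T cell RNA with 9 of 9 higher, 1 passing and 5 over the list alone. Fc receptor and phagocytosis genes rose (8 of 10 higher, 2 passing; 2 up and 1 down over the list alone), and so did inflammatory cytokines and NF-kB targets (8 of 8 higher, 1 passing, Icam1). Each of these 5 lists had adjusted p = 0.0438, and adjusted p = 0.317 with an estimated correlation. Macrophage RNA had 8 of 8 members higher in the same sums (0.154, median 0.65). Proliferation genes had 23 of 25 lower with 2 falling, Mki67 and Top2a (list 0.274, median -0.40), and hypoxia and glycolysis genes 19 of 21 higher with 3 rising, Gapdh, Slc2a1 and Ankrd37 (0.152). The exhaustion list pointed up at 0.889 with Tigit falling, median -0.01 and mean 0.01. Mitochondrial transcripts pointed down at 0.857 with 3 falling, median 0.17 and mean -0.13. In all 156 genes rose and 398 fell (554 of 8954). This became 264, 195 and 221 without Control tumours 1, 2 and 3, 0 with the run or the split, 195 with the length trend removed and 832 with only the compared groups. The lists fell to 0 with each of the run, the split and the length trend removed, to 0 without Control tumour 2 or 3 or Bispecific tumour 20, 23 or 24, to MHC class I without Control tumour 1 and to MHC class I and Fc receptor genes without Bispecific tumour 22. Inflammatory cytokines and NF-kB targets were lost without each tumour in turn.

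The bispecific antibody was compared with Combination to ask whether the form of giving both specificities matters. In macrophage-like cells (n = 5 against 5) red blood cell RNA lay lower without passing: Hbb-bt was at -3.69 ± 0.87 (12.8 against 183 CPM, adjusted p = 0.802) and Alas2 at -2.71 ± 0.70 (0.802). The erythrocyte list had 5 of 5 members lower (0.0786, 5 over the list alone), and the tumour and stroma list 6 of 8 lower (0.0786, 4 over the list alone), with Col3a1, a fibroblast collagen, at -0.96 ± 0.30 and Sparc at -0.82 ± 0.26 (each 0.947). Camera with an estimated correlation gave 0.0554 for both. MHC class II genes had 10 of 11 higher (0.392), among them H2-DMb1 at 0.42 ± 0.12 (0.947), and type I interferon-stimulated genes 26 of 28 lower (0.922). Slc37a2 in CD8 T-like cells (n = 5 against 4), a sugar-phosphate transporter, was at 1.22 ± 0.24, Hbb-bt at -5.62 ± 0.94 and Hba-a2 at -5.71 ± 0.97 (each adjusted p = 0.0625), and type I interferon-stimulated genes had 25 of 27 lower (0.673).

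Neither class held a passing gene for Bispecific against Combination. edgeR gave 0 and 0, with 547 and 632 at unadjusted p under 0.05, and DESeq2 gave 0 and 4. Without the expression filter 2 genes passed in CD8 T-like cells, at Leiden resolution 0.5 there were 4, and without Combination tumours 16, 18 and 19 there were 3, 5 and 5. Without Combination tumour 19, tumour and stroma RNA fell as a list in macrophage-like cells (0.0191).

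Barcodes with more than 50% of their UMIs from haemoglobin genes, the RNA of red blood cells, were counted beside these results. They made up 0.776 ± 0.16% of barcodes in Control (n = 4), 9.69 ± 12% in aCD47 (n = 4), 1.55 ± 0.783% in aPDL1 (n = 5), 8.42 ± 1.35% in Combination (n = 5) and 1.91 ± 0.646% in Bispecific (n = 5). Combination minus Control was 7.65 points and Bispecific minus Combination -6.51 points (each exact p = 0.00794, adjusted p = 0.0476). Adjustment here ran over haemoglobin-dominated and mitochondria-dominated barcodes in the 6 comparisons, fewer tests than for the cell shares. aCD47 minus Control was 8.92 points (exact p = 0.0286, adjusted p = 0.0571), 3.03 points without aCD47 tumour 7, which stood at 27.3% (exact p = 0.0286) and 8.84 to 8.95 points without 1 Control tumour (each exact p = 0.171), and Bispecific minus Control 1.13 points (0.0238, adjusted p = 0.0571).

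**Figure D4:**
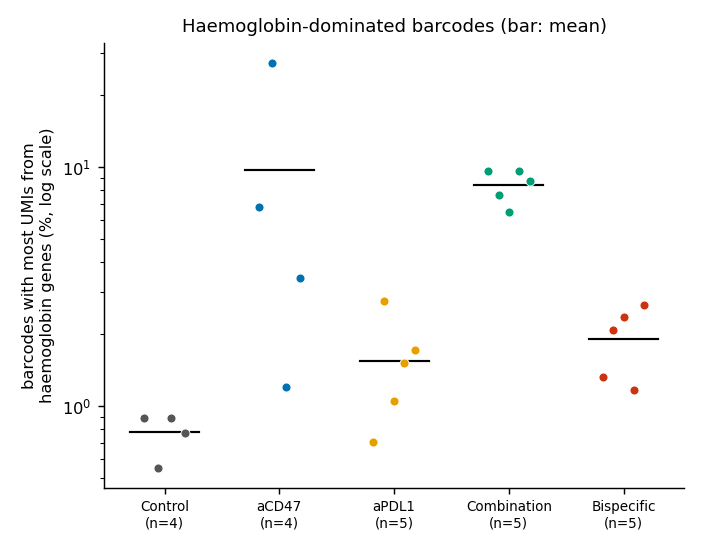
Haemoglobin-dominated barcodes as a share of all barcodes per tumour, log axis, with the mean as a bar. Mean shares were 0.776% in Control, 8.42% in Combination and 1.91% in Bispecific.

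The groups given both specificities were compared with the groups given 1 to ask what joint targeting adds. In macrophage-like cells (n = 10 against 9) Gdf15, a stress-induced cytokine (chr8:70629393-70632456), rose by 1.12 ± 0.30 (adjusted p = 0.019), the chemokine gene Pf4 (chr5:90772435-90773383) by 0.90 ± 0.19 (449 ± 156 against 247.5 ± 97.9 CPM, 0.00437), Gas6, a bridge to dying cells, by 0.84 ± 0.16 (0.00201), Igfbp4 by 0.73 ± 0.19 (0.0138), Ctsd by 0.55 ± 0.09 (0.000377), Ctsb by 0.32 ± 0.07 (0.00294) and Cd68 by 0.32 ± 0.06 (0.00052). Ifi208 fell by 0.80 ± 0.17 (0.00474), Ifih1 by 0.60 ± 0.12 (0.00214), Ifit2 by 0.55 ± 0.14 (0.0161) and Stat2 by 0.41 ± 0.09 (0.00369). The inhibitory receptor gene Havcr2 fell by 0.55 ± 0.12 (0.00416), Egr1 by 0.49 ± 0.13 (0.0169), Apc by 0.68 ± 0.10 (0.000259), Dhx9 by 0.68 ± 0.10 (0.000165) and Hist1h1e by 1.41 ± 0.25 (0.00115). The replication gene Mcm2 rose by 0.42 ± 0.11 (0.0121) while Mki67 fell by 0.69 ± 0.23 (0.0472), a call lost in 13 of 19 fits without 1 tumour (highest 0.0849, aPDL1 tumour 12). All other genes of this paragraph kept their call. Ifit2 stood at 0.08 and Dhx9 at 0.01 with the run in the fit.

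Complement, lipid and scavenger genes rose for dual against single (adjusted p = 0.00588; adjusted p = 0.454 with an estimated correlation), 17 of 20 higher, 5 passing and 8 over the list alone. Macrophage RNA rose (0.00997; adjusted p = 0.454 with an estimated correlation), 10 of 10 higher and 2 passing. T cell co-stimulation genes fell (0.0486; adjusted p = 0.915 with an estimated correlation), 10 of 14 lower and 1 passing, with 1 up and 2 down over the list alone. Type I interferon-stimulated genes had 25 of 28 lower and 5 falling without passing as a list (0.319). Mitochondrial transcripts pointed up at 0.804, median 0.16 and mean -0.07, with 5 of 13 rising (mt-Cytb by 0.29 ± 0.07, 0.00969) and 4 falling (mt-Nd6 by 0.72 ± 0.14, 0.00147). With the run these 2 genes stood at -0.03 and 0.16. In all 589 genes rose and 1021 fell (1610 of 10933), 1070 without aCD47 tumour 6, 0 with the run, 1 with the split, 0 with tumours 1 to 16 or within run 9 to 16, and 746 with the length trend removed. No list passed with the run, the split or tumours 1 to 16. Macrophage RNA was lost with the length trend removed, where complement, lipid and scavenger genes (0.0262) and co-stimulation genes (0.0397) passed, and the co-stimulation list was lost in 12 of 19 fits without 1 tumour. Without aCD47 tumour 9 tumour and stroma RNA also passed (0.0295).

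In CD8 T-like cells for dual against single (n = 9 against 9) MHC class I rose (adjusted p = 0.0109; adjusted p = 0.289 with an estimated correlation), 15 of 16 higher, 3 passing (H2-D1, H2-T23, H2-K1) and 11 over the list alone: H2-D1 by 0.27 ± 0.06 (0.0226) and H2-T23 by 0.29 ± 0.07 (0.0347). Cytotoxic genes rose (0.0355; adjusted p = 0.289 with an estimated correlation), 22 of 22 higher and none passing, and T cell RNA rose (0.0355; adjusted p = 0.289 with an estimated correlation), 9 of 9 higher, 1 passing and 8 over the list alone. Cd3e rose by 0.32 ± 0.08 (0.0315), the T cell receptor adaptor gene Lat by 0.40 ± 0.08 (0.00951), Dok2 by 0.41 ± 0.10 (0.0238) and Rac2 by 0.30 ± 0.07 (0.0176). Aspm fell by 1.19 ± 0.26 (0.019), Kif20b by 1.02 ± 0.19 (0.00746) and Mki67 by 1.12 ± 0.27 (0.0369), with 24 of 25 proliferation genes lower (list 0.244), and Tigit fell by 1.01 ± 0.24 (0.0243), Hist1h1e by 1.54 ± 0.26 (0.00746) and mt-Nd5 by 0.36 ± 0.07 (0.0111). Without 1 tumour the highest adjusted p was 0.0661 for H2-D1, 0.089 for Cd3e and 0.0505 for Rac2 (Combination tumour 18), and 0.0868 for H2-T23, 0.0596 for Dok2, 0.0591 for Tigit and 0.0841 for Mki67 (aCD47 tumour 6). Mitochondrial transcripts pointed down at 0.398, median 0.04 and mean -0.11.

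In all 60 genes rose and 195 fell in CD8 T-like cells for dual against single (255 of 8954). The count was 103, 137 and 154 without aCD47 tumours 6, 7 and 8, 157 without aPDL1 tumour 14, 399 and 93 without Combination tumours 15 and 18, and 168, 143 and 160 without Bispecific tumours 21, 22 and 24. It was 0 with the run, the split, tumours 1 to 16 or run 9 to 16, 44 with the length trend removed and 395 in DESeq2. Hist1h1e stood at 0.06 with the run in the fit. No list passed with the run or tumours 1 to 16, and with the split none of the 3 did, while dissociation and heat-shock stress genes rose (0.0289). With the length trend removed cytotoxic genes and T cell RNA were lost, MHC class I passed (0.0316) and mitochondrial transcripts fell (0.0114). MHC class I passed without each tumour, alone without aCD47 tumour 6 or 7, aPDL1 tumour 12, Combination tumour 16 or 18 or Bispecific tumour 22 or 23, and T cell RNA was lost in 9 of 18 such fits. Without aCD47 tumour 9 complement, lipid and scavenger genes also passed (0.0318). Risen genes had a median transcript length of 2057.5 bases and fallen genes 6369, all tested genes 3305.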

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

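The tests of this part were chosen only after the results were seen, except that of treatment with both antibodies on the called genes, that of other blood cells and that of UMIs per haemoglobin-dominated barcode. Over 65 groups of tumours in 13 measures, 3 held 1 tumour far from the others, and chance alone sets 1 apart in about 1 in 20 groups. In aPDL1, tumour 12 had a regulatory T-like share of 6.8% (others 1.4 to 2.71%) and tumour 14 a naive/memory T-like share of 1.97% (others 0.628 to 0.945%). In Bispecific, mitochondria-dominated barcodes made up 21.9% in tumour 22 (others 31.1 to 34.8%). Mitochondria-dominated barcodes, which enter no cell class, averaged 20.9% in Control, 28.6% in aCD47, with every tumour above the highest Control tumour (25.3%), 26.1% in aPDL1, 29.5% in Combination and 30.8% in Bispecific (10 points over Control, exact p = 0.0238, adjusted p = 0.0571, against 7.74 points, 0.0286 and 0.0571 for aCD47).

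Haemoglobin-dominated barcodes averaged 9.69% in aCD47, 8.42% in Combination and 1.91% in Bispecific, with every tumour above the highest Control tumour (0.89%, mean 0.776%). Cells were not filtered on haemoglobin. Erythroid-like cells averaged 0.0373% of kept cells in Control and 2.68% in Combination, and they count where all kept cells are the denominator. The runs of tumour numbers are argued against as the cause of the higher share with the separate CD47 antibody, since it held within runs (one-sided permutation p = 9.11e-06, the smallest of 109760 arrangements). More blood in those tumours cannot be told apart: other blood cells were 1.27 points lower in Combination than in Control (-1.27, exact p = 0.0556), which met the bound set against it in advance, but that bound was wrong by design because the CD45 beads keep red and white cells in unknown proportion. Younger red blood cells with the separate antibody stay open. Their median log2 UMIs per barcode differed by 0.173 over all tumours, and a one-sided permutation within runs gave p = 0.142. Among tumours 17 to 24 the medians were 11120 to 14620 UMIs in Combination and 11360 to 16980 in Bispecific, which is not higher with the separate antibody. Of 2 genes tested in these barcodes by permutation within runs, Alas2 gave a one-sided p of 0.00216 and Slc4a1 of 0.0683.

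The genes called with both antibodies against 1 could stem from a difference between runs of 8 tumour numbers, such as library preparation. The test below cannot tell library preparation from harvest day or other handling, as the labels assign no tumour to a batch or a day. An index of called genes was set without aCD47 tumour 9 and Combination tumours 15 and 16. In macrophage-like cells the index was -0.023 in tumour 9 and -0.561 in the other aCD47 tumours. It was 0.052 in tumours 15 and 16 and 0.513 in the other Combination tumours. A one-sided permutation gave p = 0.025 (the smallest of 40), and a one-sided permutation in CD8 T-like cells gave p = 0.0417 (the smallest of 24). Neither p can decide between run and treatment. Genes picked on the other tumours set those tumours further out than the ones left out, whatever the cause. A trend with transcript length as the whole cause is argued against in macrophage-like cells, where 590 of the 1610 genes were called again once it was removed (median log2 fold 0.312, SE 0.079, before and 0.216, SE 0.074, after). In CD8 T-like cells the count called again, 37 of 255, could not tell. The median fold of these 255 genes was 0.456 (SE 0.108) before and 0.337 (SE 0.104) after removal. Their lower quartile after removal was 0.237, with 100% in the called direction. These folds cannot decide it either, since the genes were picked for large folds in these same data. Treatment with both antibodies cannot be told apart from the runs: with the run in the fit the median fold was 0.093 with SE 0.155, and with the split after tumour 16 it was 0.186 with SE 0.146 (92.3% in the called direction), against 0.176 (SE 0.221) and 0.267 (SE 0.206) in CD8 T-like cells, so that folds shrank and their errors grew. Of the tumours given both specificities only 15 and 16 lie in a run with tumours given 1.

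The T-like share was 14.1 points higher with the bispecific antibody than with the 2 antibodies given separately. The runs of tumour numbers are argued against, since among tumours 17 to 24 the difference was 16 points (exact p = 0.0357, smallest possible 0.0179). Loss of macrophage-like cells alone cannot be told apart: among the other immune-named cells the T-like share was 16.1 points higher, with exact p = 0.103. The form in which the 2 antibodies are given stays open too, with a permutation p of 0.171 after adjustment over all share tests. That test cannot decide it, since a lone difference at the smallest possible exact p would not have passed this adjustment.

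Other ways of splitting the same tumours were counted for each gene result, the real one included. Where 0 genes were called every split gives as many by design, so the count says nothing about chance: in macrophage-like cells for aCD47 (35 of 35 splits, highest other count 1), aPDL1 (70 of 70, 3) and Bispecific against Combination (70 of 70, 1), and in CD8 T-like cells for aCD47 (35 of 35, 2), aPDL1 (56 of 56, 1) and Bispecific against Combination (100 of 100, 1). The same holds in regulatory T-like cells for aPDL1 (35 of 35, 6) and in fibroblast-like cells for aCD47 (35 of 35, 2) and Bispecific against Combination (100 of 100, 6). In macrophage-like cells no other split drawn gave as many for Combination (1 of 70, highest other 565), Bispecific (1 of 70, 315) and dual against single (1 of 70, 428). The highest other counts came from splits 1 tumour away from the real one for Combination and Bispecific (all Control tumours with Combination tumour 15 or Bispecific tumour 22) and from a split with tumours 9, 10, 12 and 18 to 24 on 1 side for dual against single. Nor did any other split in CD8 T-like cells for Combination (1 of 35, 15), Bispecific (1 of 56, 0) and dual against single (1 of 100, 1). In regulatory T-like cells Bispecific gave 1 of 35 (14), the smallest count possible. In fibroblast-like cells aPDL1 gave 9 of 100 (4), Combination 7 of 100 (7), Bispecific 2 of 100 (10) and dual against single 7 of 100 (9). For Bispecific another split there gave 10 genes, more than the 9 of the real one. For gene lists in macrophage-like cells the counts were 15 of 70 for aPDL1 (5), 2 of 70 for Combination (4), 1 of 70 for Bispecific (2) and 3 of 70 for dual against single (4). They were, in CD8 T-like cells, 4 of 35 for Combination (1), 1 of 56 for Bispecific (0) and 1 of 100 for dual against single (2). Chance stays open above all for the lists of aPDL1 and of Combination in CD8 T-like cells. Where a count is small, chance is less likely but not excluded, and the counts were not adjusted for their number. Nor do they exclude a division of the tumours by library or run of tumour numbers rather than treatment.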

How the results depend on the processing

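The fits with tumour-number runs, the split after tumour 16, the length trend removed, tumours 1 to 16 only and tumours of 1 run were chosen only after the results were seen. Of the calls on named genes, the settings fixed in advance left 1648 the same, 226 weaker and 0 reversed in sign. The later ones left 52 the same, 300 weaker and 19 reversed in sign. Leaving out 1 tumour kept 940 of 1126. Relative log expression size factors gave 795, 1225 and 1609 genes in macrophage-like and 22, 560 and 258 in CD8 T-like cells for Combination, Bispecific and dual against single, near the 801, 1225, 1610, 21, 554 and 255 of the report. In CD8 T-like cells (342214 to 3370838 UMIs per tumour, 3 Control tumours) simulated log2 folds of -1 and 1 were recovered in 49% and 68% of genes, and depth was not varied, so its part is not known. With the run in the fit 4.08% and 0% were recovered in macrophage-like cells and 0% in CD8 T-like cells, and with the split 32.7% and 34%, 12.2% and 8%, so a lost call there is partly a loss of power. Only Bispecific against Control was simulated. With the run in the fit, median estimates of simulated folds of -1 and 1 were -1.055 and 0.966 in macrophage-like cells. They were -1.102 and 0.980 in CD8 T-like cells, where folds of -0.5 and 0.5 gave -0.258 and 0.415. The simulated genes were drawn at random rather than picked by their call. These estimates therefore cannot tell why the folds of called genes shrank. Otherwise the cause of a lost call was not tested.

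In macrophage-like cells the genes with aCD47 (0) became 1 with the run, 1 with the split, 3 with only the compared groups, 1 in DESeq2 and 0 to 1 without 1 tumour. With aPDL1 (0) they became 30 in DESeq2 and 0 to 1 without 1 tumour. Combination gave 0 with the run, the split or tumours 1 to 16, 255 with the length trend removed, 473 with only the compared groups and 382 to 873 without 1 tumour. Bispecific gave 0 with the run or the split and 653 with the length trend removed. For dual against single there were 0 with the run, within tumours 9 to 16 or with tumours 1 to 16, 1 with the split, 746 with the length trend removed and 1070 to 2181 without 1 tumour.

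aPDL1 (0) in CD8 T-like cells gave 1 with only the compared groups and 0 to 1 without 1 tumour. Combination (21) gave 45 without the expression filter, 10 with the stricter cell filter, 0 with the run or tumours 1 to 16, 5 with the split, 11 with the length trend removed, 9 with only the compared groups, 114 in DESeq2 and 0 to 101 without 1 tumour. Bispecific (554) gave 0 with the run or the split, 195 with the length trend removed, 832 with only the compared groups and 195 to 570 without 1 tumour. Bispecific against Combination (0) gave 2 without the expression filter, 4 at Leiden resolution 0.5, 4 in DESeq2 and 0 to 5 without 1 tumour. Dual against single (255) gave 0 with the run, the split, tumours 9 to 16 or 1 to 16, 44 with the length trend removed, 395 in DESeq2 and 93 to 399 without 1 tumour. The 57 genes of the other classes became 14 to 83 without 1 tumour (14 without Bispecific tumour 24, 16 and 23 without Control tumours 3 and 2).

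Lists past the threshold were 0 with camera and an estimated correlation in all 7 results that had any, and 0 with the run. With tumours 1 to 16 they were 0 in each result tested that way. With the split they were 2 for aPDL1 (1 in the report), 3 for Combination (only 1 of its 4 in the report), 0 for Bispecific and dual against single in macrophage-like cells, and 0, 0 and 1 (none of the 3 in the report) for Combination, Bispecific and dual against single in CD8 T-like cells. With the length trend removed they were 2 for Combination and 1 for Bispecific in macrophage-like cells and 0 for both in CD8 T-like cells, and 2 for dual against single in each class (2 of 3 and 1 of 3 in the report). Without 1 tumour the ranges were 1 to 4 (aPDL1), 2 to 6 (Combination), 1 to 4 (Bispecific) and 0 to 1 (Bispecific against Combination) in macrophage-like cells, and 0 to 1, 0 to 4 and 1 to 4 for Combination, Bispecific and dual against single in CD8 T-like cells.

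The macrophage-like share of Combination minus Control was -0.126 points with all kept cells as denominator, against 4.8, since the non-immune share then enters. With the run in the fit the estimates of these log2 folds changed sign: in macrophage-like cells with Bispecific Ifih1 0.04, Ifit2 0.09, Stat2 0.08, Lilrb4a 0.44, Slfn9 0.07, mt-Co2 -0.03 and mt-Nd6 0.22, and for dual against single Ifit2 0.08, Dhx9 0.01, mt-Cytb -0.03 and mt-Nd6 0.16. Within tumours 9 to 16 Ifit2 was at 0.10 and mt-Nd6 at 0.12, and with the split mt-Cytb was at -0.01. In CD8 T-like cells with Bispecific the run gave Tapbp -0.17, Hist1h1e 0.18 and mt-Nd6 0.41 and the split Tapbp -0.06, and for dual against single the run gave Hist1h1e 0.06. Median standard errors with the run were 0.370 in macrophage-like and 0.560 in CD8 T-like cells for simulated unchanged genes of Bispecific against Control. For the genes called for dual against single they were 0.155 and 0.221. Most of the values with the run lie within such errors, so their sign is not settled.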

Other observations

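The tests of ratios among T-like cells, of red cell genes and of histone and other genes in further classes were chosen only after the data were seen, apart from the gene tests of the further classes, which were planned. Among T-like cells, CD8 T-like cells made up 54.4 ± 15.5% in Control (n = 4) and 73.3 ± 6.37% in Bispecific (n = 5), a difference of 18.9 points (exact p = 0.00794), with 66.6% in aCD47 and 66.5% in aPDL1 and in Combination. Control tumour 4 widened this difference, with 16 CD8 T-like of 48 T-like cells. The counts were 77 of 148, 57 of 86 and 62 of 94 in Control tumours 1, 2 and 3. Regulatory T-like cells, which restrain other T cells, made up 29.4 ± 5.75% of T-like cells in Control, 18.4 ± 4.74% in Bispecific (-11 points, exact p = 0.0159) and 17.2% in Combination (-12.2 points, exact p = 0.0397). In haemoglobin-dominated barcodes Slc4a1, the anion exchanger of the red cell membrane, was at 4.98 ± 9.97 UMIs per 1e6 in Control (SD; 0 in 3 of 4 tumours), 51.7 ± 24.6 in aCD47, 23.3 ± 34.3 in aPDL1 (8.5 without tumour 10), 94.5 ± 59.2 in Combination and 107 ± 79.2 in Bispecific. Bispecific minus Control was 102 (exact p = 0.0159), 67.2 without Bispecific tumour 20 (exact p = 0.0286) and 101 to 107 without 1 Control tumour (exact p 0.0536 to 0.0714). Alas2 was at 1930 ± 152, 2300 ± 298, 2120 ± 134, 2740 ± 351 and 2850 ± 130 (Bispecific minus Control 921, exact p = 0.00794). Control and Bispecific share no run of tumour numbers, and Bispecific minus Combination was 12.7 for Slc4a1 (exact p = 0.786) and 107 for Alas2 (exact p = 0.524). Runs 1 and 2 hold no Bispecific tumour. Within them, aCD47 and Combination tumours against the rest gave one-sided permutation p of 0.0204 for Slc4a1 and 0.00714 for Alas2, which says nothing on the bispecific antibody. Tfrc, the transferrin receptor gene of immature red cells, was at 0, 5.74, 0, 4.36 and 2.43 in pooled barcodes. These values rest on few UMIs of Tfrc, at most 29 in a tumour (aCD47 tumour 7) and at most 4 in a Bispecific tumour (tumour 24). They also rest on unequal totals, with 7154872 UMIs in these barcodes of aCD47 tumour 7 and at most 150483 in a Control tumour.

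In regulatory T-like cells with Bispecific against Control (n = 4 against 3), 4 of 4390 genes rose and 41 fell (edgeR). These make up most of the 57 genes called over the further classes, a total that fell to 14 without Bispecific tumour 24. Tgtp2 fell by 1.45 ± 0.28 (adjusted p = 0.00637), Iigp1 by 0.90 ± 0.18 (0.00856) and Slfn5 by 1.48 ± 0.33 (0.0213), as did Hist1h1e by 1.97 ± 0.36 (0.00332), Atrx by 0.96 and Dnmt1 by 1.78 ± 0.40 (0.0256), and Macf1 by 1.29 ± 0.21 (0.00147). The fall of Gm42418 by 2.41 ± 0.19 (4.66e-08) is of a gene in the same ribosomal RNA repeat as AY036118, whose split by tumour number applies here too. In fibroblast-like cells Hist1h1d fell by 3.40 ± 0.57 with Combination (0.00814) and by 2.88 ± 0.53 with aPDL1 (0.0476), and with Bispecific 1 gene rose and 8 of 5498 fell, among them Smarca5 by 0.98 ± 0.18 (0.0286) and Dhx9 by 1.53 ± 0.31 (0.0413).

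Among macrophage-like cells, 3 clusters (3, 7 and 8) had Chil3 and Tgfbi, genes of monocytes, among their leading genes. Cluster 3 held 17.1% of Control, 6.86% of Combination and 11% of Bispecific cells, cluster 7 7.97%, 4.64% and 6.4%, and cluster 8 6.1%, 3.73% and 4.83%. Clusters 0 and 12, with Mmp12 and Arg1 among their leading genes, held 16.8%, 25.3% and 17.3%, and 3.91%, 3.32% and 4.29%. UMIs per cell move with these shares: clusters 3, 7 and 8 had a median of 12165 to 16191 UMIs per cell and cluster 0 of 1838, and the median UMIs of kept cells were 2107 to 2924 in 4 of 5 Combination tumours (9295 in tumour 19) against 4463 to 6703 in Control. Among CD8 T-like cells several sub-clusters carried genes of dividing cells: sub-cluster 6, led by Hist1h2ap, Hist1h1b and Pclaf, held 17.5% of Control, 7.22% of Combination and 8.21% of Bispecific cells, sub-cluster 8, with Pclaf, Stmn1 and Mcm3, 7.55%, 9.62% and 7.08%, and sub-cluster 13, led by Ccnb2 and Birc5, 2.83%, 2.75% and 2.36%. Sub-cluster 12, at a median of 1832 UMIs and with Stmn1 and Dut, held 0.943%, 5.5% and 2.56%. These shares pool the tumours of a group and were not tested.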
